A study of Mus musculus with 2 samples.

How the data were processed

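The deposited files were raw UMI counts per gene and cell barcode, per the file headers and as whole numbers in the values, for 31053 genes in 1 EAU and 1 Control library. Per the labels, the libraries used the 10x Genomics 3' v3 kit, and eyes of 15 mice were pooled into each. The submitters' processing notes name Cell Ranger 3.0, R 4.1.3, Seurat 4.1.0 and build mm10, while the matrix header names software version 3.1.0. Alignment settings, the annotation release, the counting of intronic reads, strand use, and any correction for free RNA are not given in the sources used here. Sequence reads were not analysed here. The antigen and the clinical scores are not given in the sources used here.

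Counts were read with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, igraph 0.11.9, matplotlib 3.10.9) and R 4.3.3 with edgeR 4.0.16. Gene coordinates and transcript lengths came from GENCODE vM21 (GRCm38). Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. The UMI and gene minimum left 11232 EAU and 16893 Control barcodes, of which 2352 and 8471 lay over the mitochondrial maximum. Median mitochondrial share before filters was 12.5% in EAU and 20.0% in Control. Doublets were scored with Scrublet at an expected rate of 0.8% per 1000 barcodes. In Control the Scrublet threshold called 14.9% of barcodes, and in EAU it called 0%, so the 8.98% of EAU barcodes with the highest scores were removed by the rule set for that case. The threshold was not stable: with exact neighbours 15.5% of EAU and 30.0% of Control barcodes were called. The filters kept 71.1% of EAU and 45.6% of Control barcodes.

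Both libraries were clustered together without integration: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and cells were joined to 15 neighbours and clustered by Leiden at resolution 1. This gave 21 clusters, named from fixed markers of 29 candidate types into 14 classes. A name needed at least 3 markers, each in at least 10% of the cluster's cells and at least 2-fold over the reference level. Microglia and macrophages were kept as 1 class. Genes leading a cluster of a class, ribosomal protein, mitochondrial, haemoglobin and crystallin genes, Xist and unnamed gene models were not named as findings in that class.

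UMIs were summed per library and class and scaled to CPM, in classes with at least 50 cells in each library. Genes were named by size alone: at least 50 UMIs over both libraries, at least 50 CPM in the higher library, and at least 50% there of the level in all other cells, to limit free RNA. The 10 largest ratios each way were taken in rod-like, microglia or macrophage-like, lens-like, surface epithelium-like and cone-like cells, and 5 each way elsewhere. Between 1296 genes (surface epithelium-like) and 4222 genes (amacrine-like) qualified per class. Gene lists needed 5 members with at least 10 UMIs each. Each list median was placed among 10000 random lists of the same size and similar expression. The 29 fixed lists covered interferon, antigen presentation, chemokine, cytokine, NF-kB, complement, gliosis, cell death, metabolism and cell-type functions; medians of those not printed in the report are not reported here. T cell genes (24) were given as shares of cells with a UMI, unthinned and thinned to 1000 UMIs, and 30 ligand and receptor pairs as levels per class.

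With 1 library per group, no test between groups was possible and none was run. Intervals cover counting error only, not differences between mice, pools or preparations. The interval and list methods were tested on simulated data: class sums were drawn with Poisson noise around the mean level of both libraries, with 200 genes of each class set 2-fold or 4-fold apart. Intervals held the true ratio for 95.4% (rod-like) to 96.8% (bipolar-like) of genes, and 2-fold genes were recovered at a median log2 of 0.94 (RPE-like) to 1.04 (amacrine-like). At 4-fold the medians were 1.95 (RPE-like) to 2.01 (rod-like). Lists made of set genes reached a percentile of 100 in each of the 9 classes, and of 100 unchanged lists between 2% (amacrine-like) and 9% (lens-like) lay outside the central 95%. The draws held no spread between cells and no gradient by transcript length, so coverage near 95% followed from the setting. They do not show that intervals or percentiles hold in the data, where UMIs of some genes lay in few cells.

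The groups, filters, clustering settings, markers, gene lists, naming rule, comparisons and first set of alternatives were fixed before the data were examined. These alternatives were no mitochondrial maximum or 10%, a minimum of 1000 UMIs, no doublet removal, Leiden resolutions of 0.5 and 2, each library clustered on its own, clustering without inflammatory genes, and cells other than rods as the denominator. For expression they were trimmed mean of M values (TMM) scaling, totals without mitochondrial and rod genes, a mean over cells, thinned cells, and a higher minimum count. Chosen after seeing the data were the scoring and tie rules for cluster names (several were tried), the joining of microglia with macrophages, the giving of list medians relative to the all-gene median with intervals from redrawn counts, and the leaving out of leading genes. So was the counting of named genes under alternatives relative to the all-gene median and with at least 10 UMIs. Also chosen then were 3 added alternatives: 1 cluster per class, random lists also matched on transcript length, and doublets called with exact neighbours. The neighbour graph was remade in double precision after a first single-precision graph proved not reproducible, and class borders of shallow EAU cells moved with it. Results for some genes are not reported here and are left out of the counts of alternatives. Which list results open each paragraph was also chosen after seeing the values.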

Results

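Single-cell RNA profiles were collected from pooled mouse eyes to compare autoimmune inflammation of the eye with the eye of naive mice. Experimental autoimmune uveitis (EAU) is a mouse model in which immunization against a retinal antigen leads to T cell-driven inflammation of the retina and uvea. The EAU library was made from 15 mice at day 16 after immunization, and the Control library from 15 naive mice. All animals were female C57BL/6 mice of 6 to 8 weeks, and eyes were digested to single cells after removal of the lens. Each group held 1 library, so there were no replicates and no difference between the groups has a replicate check. The EAU library held 42108514 unique molecular identifiers (UMIs, one per captured RNA molecule), with a median of 1708 UMIs per barcode. The Control library held 74206917 UMIs, with a median of 2004 UMIs. Barcodes with at least 500 UMIs and 200 genes numbered 11232 in EAU and 16893 in Control. After filters on depth, mitochondrial share and doublets, 8125 EAU cells and 7704 Control cells were kept, with medians of 1738 and 1771 UMIs. Values in square brackets are 95% intervals that cover counting error only. They are exact Clopper-Pearson intervals for shares, exact conditional intervals for ratios of counts, and redraws of the counts for list medians.

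The first comparison asked which cell classes made up the inflamed and the naive eye. Photoreceptors dominated both libraries, with rod-like cells at 70.4% [69.4 to 71.4] of EAU cells and 72.0% [70.9 to 73.0] of Control cells. Erythroid-like cells, red blood cells and their precursors, made up 4.78% [4.32 to 5.26] of EAU cells (388 cells) against 0.0649% [0.0211 to 0.151] of Control cells (5 cells), a ratio of 73.6 [31.3 to 228]. Surface epithelium-like cells, the keratin-expressing lining of cornea and conjunctiva, were 2.97-fold [2.53 to 3.50] more frequent in EAU, at 7.83% [7.25 to 8.43] against 2.63% [2.29 to 3.02]. Retinal pigment epithelium (RPE)-like cells, which support photoreceptors and recycle visual pigment, were 2.23-fold [1.84 to 2.71] more frequent in EAU, at 4.39% [3.96 to 4.86] against 1.97% [1.67 to 2.31]. Immune cells together, microglia or macrophage-like and T-like, made up 3.93% [3.51 to 4.37] of EAU cells and 4.41% [3.97 to 4.90] of Control cells, with overlapping intervals. The order of these immune shares depended on the filters: with no mitochondrial maximum they were 4.15% [3.77 to 4.55] in EAU and 3.32% [3.04 to 3.63] in Control, with a maximum of 10% they were 5.37% and 9.62%, and with at least 1000 UMIs 2.74% and 4.06%.

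Several classes were less frequent in EAU. Myelinating glia-like cells, identified by myelin genes, were 0.185% [0.103 to 0.304] of EAU cells against 1.73% [1.45 to 2.04] of Control cells, an EAU to Control ratio of 0.107 [0.0582 to 0.183]. Skeletal muscle-like cells were 0.283% [0.180 to 0.424] against 1.27% [1.03 to 1.55], and lens-like cells 2.79% [2.45 to 3.18] against 8.19% [7.59 to 8.83], although the lens had been removed in both groups. T-like cells numbered 11 in EAU (0.135% [0.0676 to 0.242]) and 27 in Control (0.350% [0.231 to 0.510]), with intervals that overlapped narrowly. Their EAU to Control ratio was 0.386 [0.173 to 0.805], below 1 by counting error alone. With no mitochondrial maximum it was 0.553 [0.248 to 1.15]. Cone-like cells, the color photoreceptors, were 2.10% [1.80 to 2.44] against 3.54% [3.14 to 3.98], and amacrine-like interneurons 1.03% [0.825 to 1.28] against 1.90% [1.60 to 2.22]. Intervals also overlapped for microglia or macrophage-like cells (3.79% [3.39 to 4.23] and 4.06% [3.63 to 4.53]), bipolar-like cells (0.960% and 0.701%), fibroblast-like cells (0.788% and 1.08%) and Müller glia-like cells (0.505% and 0.545%). The yield of each class after dissociation can set all of these shares, and the maximum of 20% mitochondrial UMIs removed 20.9% of EAU barcodes and 50.1% of Control barcodes. With no maximum, clustering also gave a retinal ganglion-like class, which the main filter left without a named cluster. It held 33 of 10223 EAU cells and 1876 of 14382 Control cells, a ratio of 0.0247 [0.0170 to 0.0349]. In that setting 29.3% of EAU cells and 10.0% of Control cells were unnamed. The class was named only when barcodes over the maximum were kept, so its ratio is not read as a loss of ganglion cells in EAU. With a maximum of 10% the log2 share ratio was 0.45 for surface epithelium-like cells and 0.18 for RPE-like cells, and with each library clustered on its own the skeletal muscle-like ratio turned to 1.21 in favor of EAU.

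**Figure D1:**
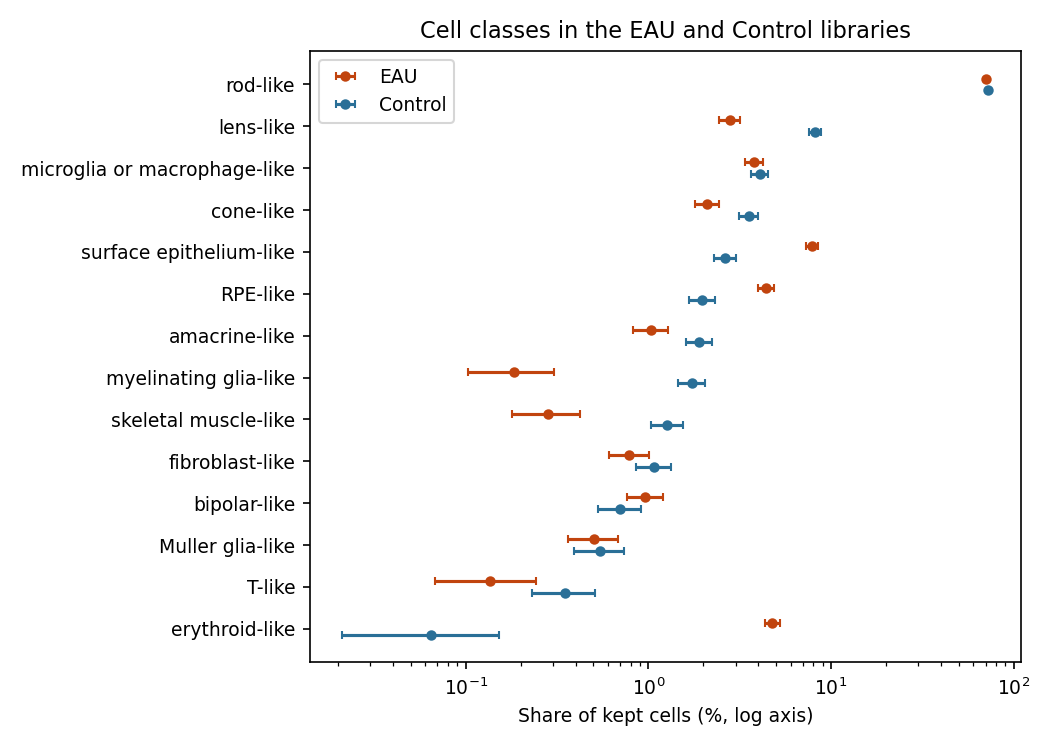
Share of kept cells (percent, log axis) in each named class of the EAU and Control libraries, with exact 95% binomial intervals as bars. Erythroid-like cells lie furthest apart, at 4.78% and 0.0649%, and rod-like cells lie close together, at 70.4% and 72.0%.

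Classes held mainly by 1 library were described within that library. In EAU, erythroid-like cells held Bpgm, which makes the haemoglobin ligand 2,3-bisphosphoglycerate, at 950 CPM (UMIs scaled to a common total) against 49.0 CPM in the other EAU cells. Fech, the last enzyme of haem synthesis, stood at 185 CPM against 9.20 CPM. Haemoglobin RNA was also spread over other EAU cells, since 78.1% [77.0 to 79.2] of EAU rod-like cells held UMIs of at least 2 haemoglobin genes against 0.253% [0.138 to 0.423] of Control rod-like cells. In Control, myelinating glia-like cells held Gatm, an enzyme of creatine synthesis, at 1322 CPM against 10.4 CPM in the other Control cells, and Ppp1r14a, a phosphatase inhibitor, at 1048 CPM against 6.11 CPM. Skeletal muscle-like cells held Pvalb, the calcium buffer of fast fibers, at 4038 CPM against 7.42 CPM in Control.

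The second comparison asked how expression within each class differed between EAU and Control, in 9 classes with at least 50 cells in both libraries. UMIs were summed per library and class, and single genes are given as measured CPM ratios. The median log2 ratio of all measured genes was -0.17 in rod-like, -0.43 in microglia or macrophage-like, 0.43 in lens-like, 0.35 in surface epithelium-like, -0.10 in cone-like and 0.12 in bipolar-like cells, and within 0.1 of 0 in the other 3 classes. List medians are therefore relative to the class's all-gene median, with the percentile of the measured median among 10000 random lists matched on expression, as a description of these libraries. Ratios called relative are divided by the same shift. A gene with 0 UMIs in 1 library has its ratio bounded against 3 UMIs.

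In rod-like cells, interferon-responsive and MHC class I antigen-presentation genes were higher in EAU. The interferon-gamma induced list had a relative median of 2.52 [2.16 to 2.71], with 22 of 26 members at least 2-fold higher, 0 lower and a percentile of 100. Psme1, a subunit of the interferon-induced proteasome activator, stood at 40.8 CPM against 13.9 CPM (2.93-fold). The MHC class I list had a relative median of 2.20 [1.82 to 2.41], with 9 of 11 members at least 2-fold higher and a percentile of 100. H2-D1, a classical class I heavy chain, was 7.22-fold [6.49 to 8.06] higher (181 CPM against 25.1 CPM), and B2m, its light chain, 2.69-fold [2.38 to 3.05] (63.4 CPM against 23.6 CPM). Outside the rod-like cells these genes were far more abundant, H2-D1 at 2349 CPM in EAU and 797 CPM in Control and B2m at 544 and 977 CPM. The level in rod-like cells reached 50% of the level in all other cells for 8 of the 26 interferon-gamma members and 2 of the 11 MHC class I members. Class I genes are close paralogs, so the split of reads between them is uncertain.

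Glycolysis and mitochondrially encoded genes also stood apart from random lists in rod-like cells, glycolysis as in most other classes. All 18 glycolysis genes lay within 2-fold as measured, but their relative median was 0.75 [0.70 to 0.77] with a percentile of 100. Over random lists also matched on transcript length the excess was 0.43 for glycolysis and 0.49 for the type I interferon list. The 13 mitochondrially encoded genes lay on the other side (relative median -0.13 [-0.14 to -0.12], percentile 0.17), and the median mitochondrial share of rod-like cells was 11.5% in EAU and 15.0% in Control. Cells had been filtered on mitochondrial UMIs, and that maximum of 20% removed 20.9% of EAU and 50.1% of Control barcodes. The size of this difference therefore depends on the filter. Gapdh was at 5790 CPM against 3816 CPM (1.52-fold, relative ratio 1.71), and Aldoa at 3567 CPM against 2016 CPM (1.77-fold [1.74 to 1.80], relative ratio 1.99). The rod phototransduction list had a relative median of 0.30 [0.27 to 0.33] and lay just below the central 95% of random lists (percentile 2.47), but inside it among lists also matched on transcript length (percentile 61.3). Rgs9, which speeds recovery from the light response, was an exception at 332 CPM against 977 CPM, 2.94-fold [2.84 to 3.05] lower in EAU. Type I interferon induced genes had a relative median of 0.75 [0.50 to 1.15] and a percentile of 99.9, with Irf7 2.54-fold [2.04 to 3.18] and Ifitm3 2.34-fold [2.02 to 2.72] higher, and 0 of its 16 members reached 50% of their level outside rods. Glul, the glutamine synthetase of Müller glia, was 2.26-fold [2.19 to 2.34] higher in EAU rod-like cells.

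Among the genes of rod-like cells that passed the naming rule, which H2-D1 and haemoglobin genes did not, the highest EAU to Control ratio belonged to Bc1 (ENSMUSG00000115783, chromosome 7, 144914470 to 144914637, GRCm38), a short brain cytoplasmic RNA annotated as lincRNA, at 892 CPM against 134 CPM, 6.67-fold [6.36 to 6.99]. Prdx6, a peroxidase of lipid peroxides, was 3.14-fold [2.90 to 3.40] higher, the metallothionein gene Mt2 2.87-fold [2.51 to 3.28], and the cytochrome c oxidase subunit gene Cox4i2 3.44-fold [3.02 to 3.94]. Fxyd6 (3.30-fold), Tomm6 (2.90-fold) and S100a1 (2.69-fold) were also among the highest. AY036118 (ENSMUSG00000105361, chromosome 17, 39847113 to 39848035), annotated as lincRNA, was 6.38-fold [6.24 to 6.52] lower in EAU, at 710 CPM against 4526 CPM. The long nuclear RNAs Tsix and Kcnq1ot1 were 5.63-fold [4.85 to 6.57] and 5.01-fold [4.51 to 5.57] lower, and both lie antisense to other genes, so their reads are uncertain. Hist1h1e, a linker histone, was 4.87-fold lower and Pclo, a presynaptic scaffold, 3.91-fold [3.52 to 4.37], with D10Wsu102e, Sik2, Paxbp1, Syt14 and N4bp2 between 3.64-fold and 4.46-fold lower. Different clusters held most rod-like cells of each library, clusters 0 and 3 in Control (4197 and 1275 cells) and clusters 1, 2 and 4 in EAU (2743, 2151 and 674 cells). Within cluster 0 alone, which held 99 EAU cells, the all-gene median was 0.70, and relative to it Mt2 (-0.74), Tsix (1.33), Kcnq1ot1 (0.59) and Sik2 (0.16) had the opposite sign, on 1 to 4 EAU UMIs each. With each library clustered on its own the interferon-gamma median of rod-like cells was 1.92. The difference was graded by transcript length: the median log2 ratio of rod-like cells was 0.34 for the shortest 25% of transcripts and -0.67 for the longest 25%.

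**Figure D2:**
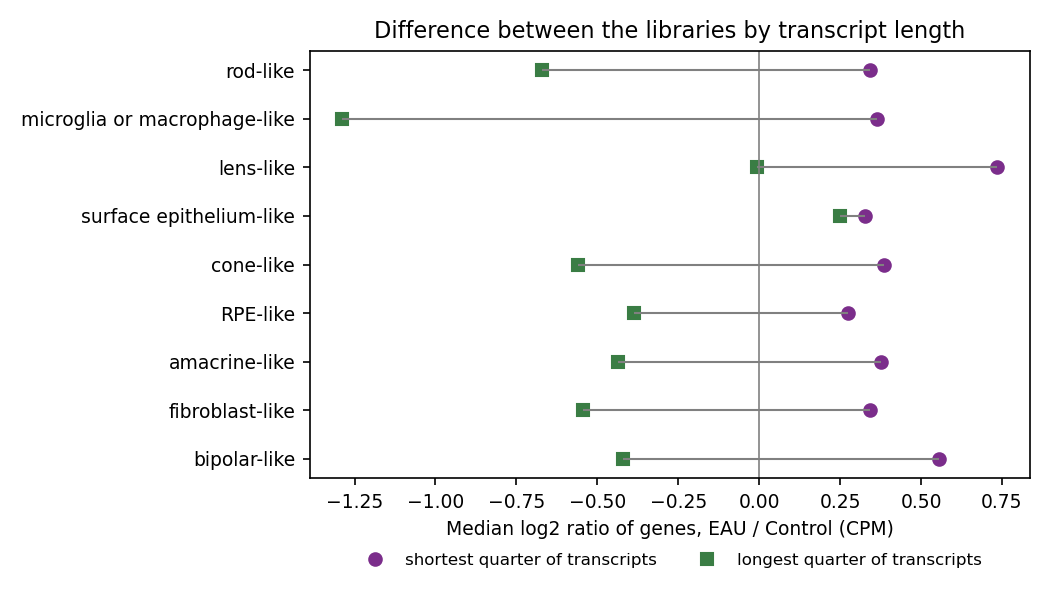
Median log2 ratio (EAU over Control) of genes in the shortest and longest 25% of transcripts, for each compared class. The 2 sets lie furthest apart in microglia or macrophage-like cells, by 1.65 (0.36 and -1.29). They lie 1.02 apart in rod-like cells (0.34 and -0.67) and 0.0778 apart in surface epithelium-like cells.

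**Figure D3:**
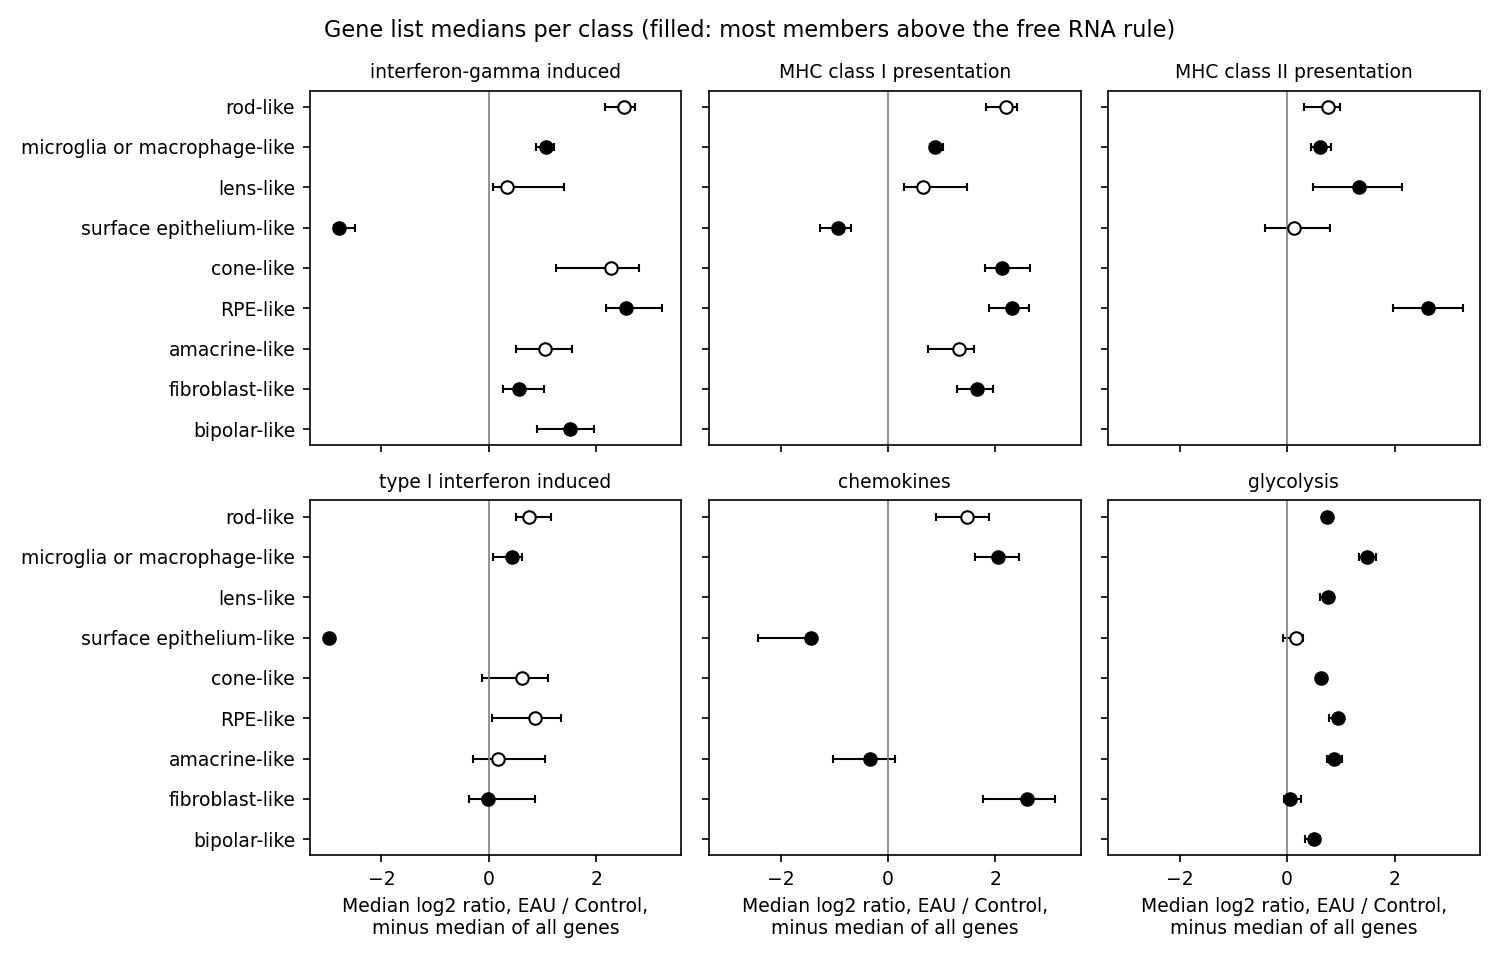
Median log2 ratio (EAU over Control) of fixed gene lists in each compared class, minus the median of all genes in that class, with 95% intervals from redrawn counts as bars. Filled points mark lists with most members above 50% of their level outside the class, the interferon-gamma list lies at 2.52 in rod-like cells, and the type I list at -2.97 in surface epithelium-like cells.

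In microglia or macrophage-like cells, the resident and recruited phagocytes of the eye, chemokine and interferon-gamma induced genes were higher in EAU and resting microglia genes lower. The chemokine list had a relative median of 2.05 [1.61 to 2.44], with 11 of 17 members at least 2-fold higher and 0 lower, and a percentile of 100. The excess over length-matched lists was 1.25. Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799), a monocyte and T cell attractant, stood at 477 CPM against 4.33 CPM (110-fold [49.9 to 303]), with its 242 EAU UMIs in 20 cells. Cxcl9, a CXCR3 ligand induced by interferon-gamma, stood at 585 CPM [521 to 656] against 39.0 CPM [29.3 to 50.8], and Ccl12 was 2.30-fold [1.95 to 2.71] higher. The homeostatic microglia list had a relative median of -1.43 [-1.65 to -1.10], with 9 of 12 members at least 2-fold lower and a percentile of 0. Cx3cr1, the fractalkine receptor of microglia, stood at 248 CPM in EAU against 1275 CPM in Control, 5.13-fold [4.28 to 6.20] lower.

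The interferon-gamma list of these phagocytes had a relative median of 1.06 [0.88 to 1.21] and a percentile of 99.96, with 7 of 26 members at least 2-fold higher and 3 lower. The type I interferon list did not stand apart, with a relative median of 0.44 [0.08 to 0.61], 2 of 17 members at least 2-fold higher, 4 lower and a percentile of 85.5. Psmb8, a subunit of the immunoproteasome, was at 499 CPM against 317 CPM (relative ratio 2.12), and Bst2, a membrane tether of viruses, at 404 CPM against 253 CPM (relative ratio 2.16). NF-kB targets had a relative median of 0.82 [0.52 to 1.05] and a percentile of 97.9, with the NF-kB inhibitor gene Nfkbia 2.76-fold [2.37 to 3.21] higher. Glycolysis genes had a relative median of 1.49 [1.34 to 1.66], with 10 of 18 at least 2-fold higher, among them Aldoa (3.21-fold [2.89 to 3.57]) and Gapdh (2.46-fold [2.30 to 2.64]). The disease-associated microglia list had a relative median of -0.94 [-1.05 to -0.60], with 10 of 17 members at least 2-fold lower. Ctsd, a lysosomal protease, was 2.85-fold [2.66 to 3.05] lower, while Lgals3, a galectin of activated phagocytes, was 2.05-fold [1.79 to 2.35] higher. Ccr2, the receptor that draws monocytes from blood, stood at 39.4 CPM against 274 CPM, 6.96-fold [4.44 to 11.5] lower in EAU.

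The largest single-gene ratios of microglia or macrophage-like cells rested on few cells. At Leiden resolution 0.5 a separate cluster of 4 EAU and 21 Control cells was named neutrophil, but Control cells of the whole class held 1 UMI of S100a9 and 3 of S100a8, so its Control cells did not carry these markers and its share is not read as one of neutrophils. These genes are not read as a difference of microglia or macrophages either. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), a calcium-binding protein of neutrophils, had 2763 EAU UMIs in 15 cells, 99.6% of them in 5 cells, and 1 Control UMI, a ratio of 7547 [1353 to 298183]. S100a8, its partner, had 2750 UMIs in 13 cells, 99.7% of them in 5 cells, against 3 UMIs. Retnlg, a further neutrophil gene, had 354 UMIs in 4 cells against 0 (at least 322-fold higher), and Wfdc21 130 UMIs in 5 cells against 0 (at least 118-fold higher). The cytokine gene Il1b was 17.5-fold [12.6 to 24.7] higher with UMIs in 14 cells of each library, and Cxcl2 42.9-fold [29.8 to 63.9] higher with UMIs in 9 EAU cells. Lcn2, G0s2, Slpi and Acod1, the last the enzyme that makes itaconate, were 36.9-fold to 68.8-fold higher with UMIs in 4 to 7 EAU cells. In the other direction, Frmd4a was 13.4-fold [6.69 to 31.2] lower in EAU (8 UMIs against 292). Adamts1 (1 against 163 UMIs), Gpr141 (2 against 156), Adcy7 (2 against 129), Alcam (2 against 106) and Cep170 (3 against 110) had Control to EAU ratios of 59.7 [10.6 to 2371], 28.6 [7.77 to 238], 23.6 [6.41 to 197], 19.4 [5.24 to 162] and 13.4 [4.47 to 66.1]. Igkc, an immunoglobulin light chain gene, and Retnla each had 0 EAU UMIs and all their Control UMIs in 2 cells. The median log2 ratio of this class was 0.36 for the shortest 25% of transcripts and -1.29 for the longest 25%, the widest gap of the compared classes. Whether this gradient contributes to the genes lower in EAU was not tested.

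Markers of other cells also differed within this class. The rod phototransduction list had a relative median of 1.76 [1.66 to 1.90] in microglia or macrophage-like cells, and rod markers stood at 72.7% of their level outside the class in EAU against 23.3% in Control. The RPE visual cycle and pigment list had a relative median of 1.99 and a percentile of 100 there, and lens markers stood at 139% of their outside level against 22.4% and myelinating glia markers at 133% against 25.9%. Most of that contrast came from lower levels outside the class in EAU, since within it lens markers stood at 2034 CPM against 1654 CPM and myelinating glia markers at 633 CPM against 817 CPM. Erythroid markers stood at 23.6% of their outside level in EAU and 3.09% in Control. In EAU, 297 of the 308 cells lay in cluster 8 (median 1015 UMIs), while in Control 203 lay in cluster 8 (1342 UMIs) and 110 in the deeper cluster 17 (8085 UMIs). Within cluster 8 alone the homeostatic microglia median was -0.50, and Cxcl2 had 7 UMIs in each library and Slpi 3 and 0, too few to give a ratio.

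In surface epithelium-like cells the direction was the opposite, with interferon and inflammatory genes lower in EAU than in Control. The type I interferon induced list had a relative median of -2.97 [-3.02 to -2.90], with 15 of 17 members at least 2-fold lower and 0 higher, and the interferon-gamma list -2.78 [-2.89 to -2.48], with 16 of 25 lower and 0 higher. Both had a percentile of 0. With every cell thinned to 1000 UMIs the interferon-gamma median was -0.77 and the type I median -2.34. Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680), an interferon-induced gene, stood at 14.8 CPM against 1871 CPM, 126-fold [111 to 144] lower in EAU. Ifitm3, which blocks virus entry, stood at 139 CPM against 2095 CPM (15.0-fold [14.3 to 15.7] lower) and Isg15, a ubiquitin-like interferon product, at 2672 CPM against 6863 CPM (2.57-fold [2.53 to 2.60] lower). Irf7 and Psmb8 lay near the all-gene median (relative EAU to Control ratios 0.957 and 1.04).

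Interferon genes themselves were counted in Control epithelium, and whether the naive mice were free of infection of the eye surface is not given in the sources used here. Ifnl2 (ENSMUSG00000059128, chromosome 7, 28508836 to 28510455), an interferon-lambda, had 2551 Control UMIs in 24 cells against 2 in EAU, a ratio of 3454 [955 to 28538]. Ifnl3, a near copy beside it, had 1487 UMIs in 20 cells against 2, so the split of reads between them is uncertain. Ifnb1 (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), interferon-beta, had 343 UMIs in 3 Control cells and 0 in EAU (at least 310-fold lower). Cxcl10 was 232-fold [129 to 466] lower in EAU, with UMIs in 4 EAU and 9 Control cells. Slfn4 and Slfn1, interferon-induced Schlafen genes, were 70.5-fold [59.1 to 84.8] and 41.3-fold lower, and Ifi207 22.2-fold [17.6 to 28.2]. The hypoxia-induced lipid droplet gene Hilpda was 45.3-fold [33.3 to 63.2] lower and the mucosal keratin gene Krt4 27.5-fold [20.3 to 38.1].

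Inflammatory lists of the surface epithelium-like cells lay in the same direction. Inflammatory cytokines had a relative median of -2.09 [-2.15 to -1.71], chemokines -1.43 [-2.42 to -1.35], NF-kB targets -1.14 and MHC class I genes -0.94 [-1.26 to -0.68], with percentiles of 0, 0.03, 0.01 and 0.38. Tnf stood at 276 CPM in EAU against 918 CPM (3.32-fold [3.19 to 3.46] lower), Il1a at 152 CPM against 771 CPM (5.06-fold [4.81 to 5.32] lower) and Nfkbia at 1033 CPM against 4402 CPM (4.26-fold [4.18 to 4.35] lower). B2m was 3.52-fold [3.42 to 3.62] lower, while Nfkb2 was 2.64-fold [2.17 to 3.24] higher. Zbp1, a nucleic acid sensor of necroptosis, was 6.64-fold [6.20 to 7.11] lower in the cell death list (relative median -0.82, percentile 1.08).

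Other genes were higher in EAU epithelium. Krt17 (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029) and Krt16, keratins of stressed and proliferating epithelium, were 21.2-fold [15.1 to 30.9] and 9.38-fold [7.87 to 11.3] higher, with 78.6% of the Krt17 UMIs in 5 cells. Insig1 (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662), a brake on sterol synthesis, was 6.17-fold [5.83 to 6.53] higher at 1412 CPM against 229 CPM. The heat shock gene Hspa1a was 15.2-fold higher, the Notch target Hes1 9.71-fold [7.16 to 13.5], Txnip, a glucose-responsive arrestin, 8.42-fold [6.66 to 10.8], and the adhesion gene Nectin4 6.26-fold [5.37 to 7.33], while Lce3c, Slc16a11 and Pon2 were 6.29-fold to 9.74-fold higher. The endothelial barrier list had a relative median of 0.81 [0.46 to 1.23] and a percentile of 99.6, with the tight junction gene Ocln 4.67-fold [3.46 to 6.42] higher. Rod markers stood at 2.81% of their outside level in EAU and 2.55% in Control in these cells, which had medians of 28214 and 31679 UMIs.

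In RPE-like cells, genes of interferon-gamma response and of both antigen-presentation pathways were higher in EAU. The interferon-gamma list had a relative median of 2.55 [2.18 to 3.22], with 17 of 21 members at least 2-fold higher and 1 lower, the MHC class I list 2.31 [1.87 to 2.62], with 7 of 9 higher, and the MHC class II list 2.62 [1.98 to 3.27], with 5 of 6 higher. All 3 had a percentile of 100. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the class II invariant chain, had 89 UMIs in 42 EAU cells against 2 in Control, a ratio of 71.3 [19.2 to 598], and H2-Aa 19 against 0 (at least 10.2-fold higher). Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634) and Irgm1, interferon-inducible GTPases, had ratios of 64.1 [17.2 to 539] (80 UMIs against 2) and 12.7 [6.75 to 26.3].

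H2-T23, a nonclassical class I gene, was 19.2-fold [7.80 to 61.4] higher in EAU RPE-like cells, H2-D1 4.97-fold [3.58 to 7.01], H2-K1 4.17-fold [3.22 to 5.44] and Bst2 2.71-fold [2.20 to 3.35], while Gbp4 was 8.89-fold [3.29 to 33.7] lower, with its UMIs in 3 EAU and 4 Control cells. The neurofilament gene Nefh was 35.3-fold [13.3 to 132] higher, with 89.8% of its UMIs in 5 cells. AY036118 was 7.16-fold [6.65 to 7.73] lower, Dusp4, a phosphatase of MAP kinases, 5.12-fold [2.65 to 11.1], and Syap1, Cast and Gucy1a1 between 4.78-fold and 6.11-fold. NF-kB targets had a relative median of -0.66 [-1.40 to -0.28] and a percentile of 0.66, with Nfkbia 4.87-fold [3.34 to 7.33] lower. The visual cycle and pigment list had a relative median of -0.47 [-0.69 to -0.34] and a percentile of 0.21, with 3 of 13 members at least 2-fold lower. The rod phototransduction list had a relative median of 1.75 [1.66 to 1.96], and rod markers stood at 60.3% of their outside level in EAU against 13.7% in Control. Lens markers stood at 154% of their outside level in EAU and myelinating glia markers at 149% (15.8% and 16.7% in Control, where outside levels were higher), or at 2235 CPM against 1154 CPM and 708 CPM against 523 CPM within the class, so free RNA of other cells is not excluded for the genes higher in EAU RPE-like cells. Median depth was 1069 UMIs in EAU and 3169 in Control, and with each library clustered on its own the interferon-gamma median of RPE-like cells was 3.62.

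Cone-like cells shared the MHC class I difference of rod-like cells. Their MHC class I list had a relative median of 2.13 [1.81 to 2.64], with 8 of 10 members at least 2-fold higher, and the interferon-gamma list 2.28 [1.25 to 2.79], with 6 of 10 higher, both with a percentile of 100. H2-D1 was 7.19-fold [5.71 to 9.12] higher (213 CPM against 29.6 CPM) and H2-K1 6.46-fold [4.76 to 8.88]. Outside the cone-like cells H2-D1 stood at 1618 CPM in EAU and 468 CPM in Control, and 1 of the 10 interferon-gamma members reached 50% of its outside level. The immediate early gene Fos was 4.17-fold [3.22 to 5.42] higher and the small RNA host gene Snhg9 4.49-fold [3.23 to 6.29]. Bc1, Tmem59l, Tomm6, Bloc1s1, Ccl9, Phpt1 and Gstp1 were 2.65-fold to 3.59-fold higher. AY036118 was 14.2-fold lower and the synaptic scaffold gene Dlg2 5.00-fold [3.32 to 7.87]. D10Wsu102e, Tsix, Kcnq1ot1, Dpp8, Ago3, Lrit3 and Paxbp1 were 3.23-fold to 4.31-fold lower. The cone phototransduction list did not stand apart (relative median 0.48 [0.39 to 0.53], percentile 70.1).

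In lens-like cells, the genes with the largest differences were mostly held by few Control cells. Nid1 (ENSMUSG00000005397, chromosome 13, 13437551 to 13512269) and Col4a2, both basement membrane components, were 11.2-fold [5.41 to 28.1] and 9.81-fold [5.92 to 17.6] lower, and Hmox1, which degrades haem, 9.34-fold [5.63 to 16.8]. In Control, 68.8% of the Nid1 UMIs and 78.6% of the Col4a2 UMIs lay in 5 cells, and the extracellular matrix list had under 5 measured members. Folr1 and Anxa1 were 11.8-fold [5.39 to 32.4] and 8.87-fold [5.58 to 15.0] lower, and Clic5 (1 against 166 UMIs) and Fat1 (3 against 154 UMIs) had Control to EAU ratios of 29.2 [5.16 to 1159] and 9.02 [3.03 to 44.2]. Bc1 was 7.90-fold [6.58 to 9.50] higher in EAU, and Rax, a transcription factor of photoreceptors, 4.03-fold [2.83 to 5.71], with Gdpd1, Psd, Gzmm, Hpcal1, Slc25a11, Ankrd33, Gstp1 and Susd3 3.88-fold to 4.93-fold higher. The MHC class II list had a relative median of 1.34 [0.49 to 2.13], with 4 of 5 members at least 2-fold higher and a percentile of 99.9, including Cd74 at 70.2 CPM against 12.9 CPM (5.45-fold [2.89 to 10.2]). Complement genes had a relative median of -0.90 [-1.36 to -0.40] and a percentile of 1.66. Rod markers stood at 190% of their outside level in EAU lens-like cells and 65.6% in Control, and clusters 6 and 11 held 203 and 24 EAU cells against 309 and 322 Control cells. Nid1, Col4a2, Folr1 and Anxa1 were among the leading genes of a separate unnamed cluster of 14 Control cells when each library was clustered on its own, so a few such cells may carry these differences. Relative to the all-gene median, the log2 ratios of Folr1 and Anxa1 were then 0.0810 and -0.22, against -4.00 and -3.58 in the joint clustering.

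Fibroblast-like cells of EAU had higher levels of MHC class I genes, with a relative median of 1.65 [1.28 to 1.96] and 7 of 9 members at least 2-fold higher. H2-K1 stood at 821 CPM against 173 CPM (4.75-fold [3.46 to 6.58]) and B2m at 1241 CPM against 368 CPM (3.37-fold [2.69 to 4.25]). Immediate early genes had a relative median of 1.86 [0.86 to 2.51], with 9 of 15 at least 2-fold higher, and chemokines 2.59 [1.76 to 3.12], with 5 of 7. Fos was 18.1-fold [10.2 to 34.8] higher, Jun 8.62-fold [5.66 to 13.6], Junb 9.97-fold and Egr1 8.07-fold, all with over 93% of their EAU UMIs in 5 cells, and complement C3 stood at 402 CPM against 30.9 CPM. Cxcl9 was 5.24-fold [3.14 to 9.07] higher with UMIs in 4 EAU and 2 Control cells, and Cxcl13, a B cell attractant, had 46 UMIs in 2 EAU cells against 0 in Control. The interferon-gamma list had a relative median of 0.57 [0.27 to 1.02], with 9 of 22 members at least 2-fold higher and 2 lower, and a percentile of 99.99. AY036118 was 8.49-fold lower, and Rgs9, Med13, Cntln and Unc13b were 4.82-fold to 7.94-fold lower. Erythroid markers stood at 53.9% of their outside level in EAU and 0% in Control. With a mitochondrial maximum of 10% the chemokine median was 0.44 and the MHC class I median 1.00, and with each library clustered on its own the chemokine median was 0.25.

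Inner retinal neurons showed smaller sets. In amacrine-like cells the MHC class I list had a relative median of 1.32 [0.75 to 1.61], with 4 of 6 members at least 2-fold higher, and the interferon-gamma list 1.04 [0.51 to 1.55], with 4 of 9 higher and 1 lower. H2-D1 stood at 207 CPM against 75.5 CPM (2.75-fold). Bc1 was 6.07-fold [5.21 to 7.11] higher, with Zyx, Fgf1 and Gfra2 4.88-fold to 5.10-fold. Tac2, the neurokinin B precursor, had 0 EAU UMIs against 322 in 7 Control cells (at least 50.9-fold lower), and Vcan 0 against 85 in 8 cells (at least 13.4-fold lower). Maf, a transcription factor, was 11.8-fold [7.21 to 20.9] lower, AY036118 10.6-fold, and Fgd6 (3 against 66 UMIs) had a Control to EAU ratio of 10.4 [3.42 to 51.8]. Bipolar-like cells had an interferon-gamma median of 1.52 [0.90 to 1.96], with 6 of 9 members at least 2-fold higher, 5 of them given as bounds. Tmsb10, an actin-sequestering peptide, stood at 1513 CPM against 395 CPM (3.83-fold [3.16 to 4.67]), with Gzmm, Dctn6 and Vstm2b 3.64-fold to 3.93-fold higher. AY036118 was 10.6-fold [9.05 to 12.4] lower in bipolar-like cells, and Mobp, Syne2, Rock1 and Dmd 3.30-fold to 3.98-fold. Rod markers stood at 29.0% (EAU) and 17.3% (Control) of their outside level in amacrine-like cells and at 49.9% and 43.9% in bipolar-like cells.

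Across the 9 classes, the interferon-gamma list lay above the central 95% of random lists in 7, and the glycolysis list also in 7. For the interferon-gamma list the count was 4 with a mitochondrial maximum of 10%, with thinned cells and with a higher minimum count, where fewer classes could be measured.

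The third comparison asked which lineage genes T-like cells carried, from 11 EAU and 27 Control cells with medians of 6987 and 5583 UMIs. Cd4, the helper T cell coreceptor, had a UMI in 5 EAU cells (45.5% [16.7 to 76.6]) and 8 Control cells (29.6% [13.8 to 50.2]). Cd8a, the cytotoxic T cell coreceptor, had a UMI in 3 EAU cells (27.3% [6.02 to 61.0]) and 11 Control cells (40.7% [22.4 to 61.2]). Ifng, the interferon-gamma gene, had a UMI in 4 EAU cells (36.4% [10.9 to 69.2]) and 8 Control cells (29.6%), and the tissue residency receptor gene Cxcr6 in 7 (63.6% [30.8 to 89.1]) and 18 (66.7%). Il17a had a UMI in no cell of either library (upper limits of the share with a UMI 28.5% in EAU and 12.8% in Control), which at this depth does not show that no cell expressed it. The regulatory T cell factor Foxp3 had a UMI in 0 EAU cells and 1 Control cell. With each cell thinned to 1000 UMIs, which left out no cell, Cd4 had a UMI in 1 EAU and 2 Control cells, Cd8a in 1 and 8, Ifng in 3 and 1 and Cxcr6 in 3 and 6. In EAU rod-like cells, which should lack these genes (median 1665 UMIs), Cd4 was found in 0 of 5722 cells, Ifng in 2 and Cxcr6 in 3, and in Control rod-like cells (median 1691 UMIs) Cd4 and Ifng in 0 of 5544 and Cxcr6 in 29. The EAU and Control intervals of these genes overlapped, so no difference was detectable at this number of cells, and with each library clustered on its own a Control cluster of 27 cells scored highest for T cells but stayed unnamed by the tie rule.

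The fourth comparison set ligand and receptor levels of immune and retinal cells side by side. The receptor subunit gene Ifngr1 stood at 372 CPM [363 to 382] in EAU surface epithelium-like cells against 167 CPM [157 to 178] in Control, and at 101 CPM [74.8 to 132] against 289 CPM [262 to 319] in microglia or macrophage-like cells. In rod-like cells Ifngr1 was close, at 44.1 CPM [40.5 to 47.9] against 38.9 CPM [35.8 to 42.1]. Mif, an inflammatory cytokine that binds CD74, was abundant in RPE-like cells, at 2407 CPM [2282 to 2538] against 1935 CPM [1846 to 2027]. Mif also stood at 864 CPM [848 to 880.1] against 579 CPM [567 to 591] in rod-like cells and at 1784 CPM [1664 to 1911] against 883 CPM [824 to 944] in amacrine-like cells. Csf1r, the survival receptor of microglia, stood at 528 CPM [467 to 595] against 1136 CPM [1080.3 to 1193] in microglia or macrophage-like cells. In that class the deeper cluster 17 held 11 EAU and 110 Control cells. Rod markers there stood at 72.7% of their outside level in EAU against 23.3% in Control. A different mix of clusters or free RNA may thus contribute to the lower Ifngr1 and Csf1r levels of the class, which was not tested. Cd274, the PD-1 ligand, was highest in surface epithelium-like cells among the classes measured, at 684 CPM [671 to 697] against 1156 CPM [1128 to 1184]. App, another CD74 ligand, stood at 659 CPM [594 to 729] in EAU RPE-like cells against 963 CPM in Control.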

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

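The tests of this part were chosen after the result was seen. Barcodes removed by the mitochondrial maximum carried red blood cell RNA in EAU but not in Control. Of 2352 EAU barcodes over the maximum, 78.4% [76.7 to 80.0] held UMIs of at least 2 haemoglobin genes, against 0.283% [0.182 to 0.421] of 8471 Control barcodes. Kept EAU rod-like cells held them at nearly the same rate (78.1%, median 4 haemoglobin UMIs, against 0.253% and 0 in Control). Haemoglobin genes stood at 3530 CPM in the removed EAU barcodes and 2056 CPM in the kept EAU rod-like cells. Microglia markers were found in 0.893% of the removed EAU barcodes and 1.36% of the removed Control barcodes, and T cell receptor genes in 1 barcode of each. The same rate in kept and removed barcodes fits free haemoglobin RNA in the EAU suspension, but the cause was not tested.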

How the results depend on the processing

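Which alternatives moved a result is given here as log2 values, EAU over Control, unless marked as percent; the alternatives marked as added were chosen after the result was seen. Of 138 class share ratios, 111 stayed inside the main 95% interval, 26 moved out of it and 1 reversed, which here means an opposite sign where the main ratio was at least 2-fold; opposite signs of smaller ratios count as moved. Of 1131 list medians 308 moved and 2 reversed, and of 867 named-gene ratios with at least 10 UMIs, taken relative to the all-gene median, 215 moved and 7 reversed. TMM scaling and totals without mitochondrial and rod genes cancel in medians relative to the all-gene median, so they are no check of these medians or ratios and are left out of both counts. Length-matched random lists (added) moved 23 of 184 percentiles across the 95% limits. The cause was not tested for any of them.

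Cells kept (8125 EAU and 7704 Control) were 10223 and 14382 with no mitochondrial maximum, 3722 and 1684 with a maximum of 10%, 6348 and 6970 with at least 1000 UMIs, 8880 and 8422 with no doublets removed, and 7566 and 6635 with exact-neighbour doublets (added). The immune share (3.93% and 4.41%) was 5.37% and 9.62% with a maximum of 10%, 13.3% and 15.7% of cells other than rods, 4.15% and 3.32% with no maximum, and 2.74% and 4.06% with at least 1000 UMIs.

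The log2 share ratio of RPE-like cells (1.16) was 0.18 with a maximum of 10% and 0.80 with at least 1000 UMIs. That of surface epithelium (1.57) was 2.04 with no maximum, 0.45 with a maximum of 10% and 1.93 at resolution 2. That of lens (-1.55) was -1.29 with no maximum, -2.02 with a maximum of 10%, -1.96 with at least 1000 UMIs, -2.43 at resolution 0.5, -2.69 at resolution 2 and -0.70 with own clustering. That of microglia or macrophage (-0.10) was 0.37 with no maximum, -0.69 with a maximum of 10% and -0.52 with at least 1000 UMIs. That of rod (-0.03) was -0.31 with no maximum, 0.31 with a maximum of 10%, -0.59 and -0.43 at resolutions 0.5 and 2, -0.50 with own clustering and 0.0314 without inflammatory genes. Unnamed cells were more frequent in EAU where the rod ratio fell, so naming may set these lower rod shares. The EAU to Control ratio of unnamed shares was 2.92 with no maximum, 45.1 and 24.6 at resolutions 0.5 and 2, and 3.82 with own clustering. The log2 share ratio of amacrine (-0.87) was -1.99 and that of myelinating glia (-3.23) -4.58 with a maximum of 10%, and myelinating glia -4.49 at resolution 2. That of fibroblast (-0.45) was -0.99 with a maximum of 10% and 0.32 at resolution 2. That of skeletal muscle (-2.17) was -3.92 with a maximum of 10% and reversed to 1.21 with own clustering. Classes more than 2-fold more frequent in EAU numbered 3, or 1 with a maximum of 10%, and those more than 2-fold less frequent 4, or 1 with own clustering.

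The interferon-gamma induced list in rods (2.52) was 1.92 with own clustering, 2.03 thinned and 1.98 in 1 cluster (added). In microglia or macrophages (1.06) it was 0.84 with no doublets removed, 1.28 thinned and 1.32 in 1 cluster (added). In RPE (2.55) it was 3.62 with own clustering and 2.13 thinned, and in surface epithelium (-2.78) -0.77 thinned and -2.40 with a mean over cells. It lay above random lists in 7 classes, or 4 with a maximum of 10%, thinned, or with a higher minimum count. The MHC class I presentation list in rods (2.20) was 2.98 with a maximum of 10%, 1.80 with own clustering and 1.71 thinned, in RPE (2.31) 2.84 with own clustering, and in fibroblasts (1.65) 1.00 with a maximum of 10%, 2.05 thinned and 2.10 with a mean over cells. The MHC class II presentation list in RPE (2.62) was 3.32 with a maximum of 10%. The type I interferon induced list in surface epithelium (-2.97) was -2.34 thinned and -3.24 with a mean over cells. The chemokines list in fibroblasts (2.59) was 0.44 with a maximum of 10%, 0.25 with own clustering and 3.45 with a mean over cells. The homeostatic microglia list in microglia or macrophages (-1.43) was -1.68 with own clustering, -0.88 with a mean over cells and -0.50 in 1 cluster (added).

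Reversed list medians were that of homeostatic microglia genes in rods (-1.65, or 2.62 in 1 cluster, added) and of the cone phototransduction list in microglia or macrophages (1.05, or -0.12 in 1 cluster, added). Named-gene values here are relative to the all-gene median of the same setting. In rods, Mt2 (1.69) reversed to -0.74, Tsix (-2.32) to 1.33, Kcnq1ot1 (-2.15) to 0.59 and Sik2 (-1.94) to 0.16 in cluster 0 alone (added), where the all-gene median was 0.70 and 99 EAU cells, with 1 to 4 UMIs of each of these genes, stood against 4197 Control cells. Crym and Spc25, which lead a rod cluster, reversed to -0.0857 and -0.19 there. In lens, Folr1 (-4.00) reversed to 0.0810 with own clustering, on 6 EAU and 10 Control UMIs. Named genes over 2-fold apart numbered 134, or 78 with a higher minimum count.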

Other observations

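The tests of this part were chosen after the result was seen, except for the test of transcript length bias, which was set before. Glial and metabolic lists not described above also stood apart from random lists. In rod-like cells, Müller glia genes had a relative median of 0.58 [0.46 to 0.71] and gliosis genes 0.60 [0.42 to 0.93], both higher in EAU (0.29 and 0.57 over length-matched lists), with 9 members of each reaching 50% of their level outside rods. Vim, an intermediate filament gene of reactive glia, was 2.29-fold and S100a6 2.90-fold higher in EAU rod-like cells. In fibroblast-like cells the gliosis list had a relative median of 0.91 [0.69 to 1.24] and a percentile of 99.99. In amacrine-like cells the glycolysis list had a relative median of 0.86 [0.74 to 1.02] (0.57 over length-matched lists), with 5 of its members at least 2-fold higher.

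The first pattern is the higher interferon-gamma and MHC class I level in EAU photoreceptors. In rod-like cells the listed genes stood at a median of 24.9% of their level in all other cells, inside the 9.71% to 30.5% range of sets of other cell types' markers, and in cone-like cells at 21.8%, inside 3.99% to 33.9%. Free RNA of other cells therefore fits the EAU level of both and is not excluded. The test used EAU levels only, so it cannot decide what set the difference between the libraries. Outside rod-like cells H2-D1 was higher in EAU than in Control, as within them, but B2m was lower. In RPE-like cells the same genes stood at 153%, above the upper limit of 85.0% for marker sets, but in a comparison added after that result pooled lens markers stood at 154% there, so free RNA cannot be told apart from expression by the RPE. The interferon-gamma median of RPE-like cells was 2.13 with cells thinned, above the limit set for depth as the cause. Thinning is a weak test here, because UMIs were summed over the class and depth per cell does not enter such ratios directly. It also left out 156 of 357 EAU and 25 of 152 Control cells, and it does not remove free RNA. Depth is therefore not excluded by this test, and immunization itself stays open as untested.

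The second pattern is the higher interferon-induced level of Control surface epithelium-like cells. Without cells holding a UMI of Ifnl2, Ifnl3 or Ifnb1 (2 EAU and 24 Control cells) the type I median was -2.79. The UMIs of those cells therefore do not carry the type I list by themselves. Interferon is secreted, so the test cannot show whether a few such cells raised the list in the others. With cells thinned the type I median was -2.34. Median depths were close (28214 UMIs in EAU and 31679 in Control), so no sign was seen that depth accounts for the type I list. The interferon-gamma median was -0.77 with cells thinned, on the other side of the limit of -1. Only 19 members were measured then, fewer than without thinning, so the 2 medians do not cover the same genes. The test therefore cannot decide whether depth contributes to that list. The test of another mixture of epithelial clusters, as first written, came out on the side of that explanation: the median was -0.92 in the cluster where it was nearest to 0 (limit -1), which held 28 Control cells. A test added after that result gave -2.94 in the cluster with the most cells. That cluster held 478 EAU and 176 Control cells, and a changed proportion of the 2 clusters cannot give a difference inside 1 of them. These values therefore argue against such a change as the source of the type I difference in the larger cluster. Mixtures finer than these clusters were not tested and are not excluded. An infection of the naive mice was not tested either, and the pattern is not called biological.

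The third pattern is that short transcripts were higher and long or nuclear transcripts lower in EAU. The shortest 25% of transcripts had a median log2 ratio over 0.2 above the longest 25% in 8 of 9 classes, surface epithelium-like cells being the exception. The 20 genes named in rods had a median log2 ratio of 1.25 in the same direction in 3 other classes. Both a length bias of a library and a difference shared by all its cells fit, and the pattern, including Bc1, Tsix and Kcnq1ot1, could be technical. AY036118 went against the length gradient. Its coordinates span fewer than 2164 bases, the limit of the shortest 25% in rod-like cells, yet it was lower in EAU. A length bias therefore does not account for AY036118. A shared difference fits it, with relative log2 ratios of -3.45, -3.02 and -3.10 in surface epithelium-like, lens-like and fibroblast-like cells, so it could be technical too.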
